A study of Homo sapiens with 8 samples.

How the data were processed

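RNA was measured in 8 libraries of mice engrafted with the human leukaemia line MOLM14, 4 from bone marrow cells sorted for human CD45 and 4 labelled as liver pieces. Per the labels' protocols, total RNA was extracted, messenger RNA libraries were prepared and paired ends were sequenced. The deposited table holds raw gene counts of 60676 genes with Ensembl identifiers, whole numbers with a different total in each library and no normalization. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to GRCh38. The counting program, its annotation and strand setting, and whether mouse reads were separated from human reads, are not given in the sources used here, so counts of antisense and overlapping genes are uncertain. The file's own pairing of identifiers and symbols was used, and coordinates came from GENCODE 29 (GRCh38), which holds 96.4% of the identifiers.

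Groups came from the labels, which give 1 library per tissue, drug and diet. Nothing in the labels says how many animals a library represents. Genes with 10 or more counts in at least 2 of a tissue's 4 libraries were tested. Counts were scaled with TMM factors and fitted per tissue label in edgeR 4.0.16 (R 4.3.3) with robust dispersion estimates and the bias-adjusted quasi-likelihood method, with drug and diet as terms. This leaves 1 residual degree of freedom, which holds any interaction of drug and diet, and p-values therefore lean on the spread shared across genes and measure only the spread between these libraries. Two-sided p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and standard errors were derived from the fold change and the F statistic. The weight of the shared spread, in prior degrees of freedom, had a median of 47.4 in marrow. In the libraries labelled liver this median was infinite, so standard errors of most genes there rest on the shared spread alone. Log2 CPM used a prior count of 2.

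Of 43 gene lists written before the data were examined, with 883 symbols of which 881 were found, those with 5 or more tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The first estimates the correlation from the residuals. With 1 residual degree of freedom per label, and few in the fits of all 8 libraries, it had little power to call any list. A high adjusted p from it therefore does not show that a list stayed unchanged. Ratios between single libraries were described without a test, and intervals of single-gene ratios were exact conditional 95% intervals. Marker sums carry exact Poisson 95% intervals, and a count of 0 was taken to allow up to 3 counts. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

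Named genes followed a rule fixed before the data were examined: per main effect, the 10 largest increases and 10 largest decreases among called genes with the same sign in both arms of the other factor and a mean log2 CPM of at least 2, passing over clone names, long intergenic RNAs, small RNA genes and numbered pseudogenes, plus up to 3 called members of each list described and 16 genes always reported. Single-library contrasts named the 5 highest and 5 lowest ratios at 50 or more summed counts and a mean log2 CPM of at least 4. Other genes named from the lists, the shared calls and the fit of all 8 libraries were chosen after their values were seen. Some genes that met the rule are not reported here.

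Other settings chosen beforehand were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings and count filters, the older quasi-likelihood fit, a fit without the other factor, fits of all 8 libraries with separate terms per label, and each library left out of that fit. With 1 of a label's libraries left out, its drug and diet effects are ratios of single libraries, with no spread left within that label. The spread then comes from the other label, and the library left alone in its arm was assumed to vary like the others. The fit of all 8 libraries with 1 drug and 1 diet term, the tests between labels, and the counts thinned to the smallest library were added after the data had been examined.

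The fits were tested on simulated counts with 200 changed genes and 1 dispersion for all genes, which is easier than real data. For the marrow drug comparison, with 13737 genes, 68.7% of 1.5-fold changes and 98.5% of 2-fold changes were recovered, and 5.56% of calls were false. For the marrow diet comparison, with 13739 genes, 65.7% of 1.5-fold and 98.5% of 2-fold changes were recovered. For the drug comparison in the libraries labelled liver, with 13873 genes, these shares were 44.8% and 91.0%, and for the diet comparison there, with 13855 genes, 70.1% and 97.0%.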

Results

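Ketogenic feeding and the FLT3 inhibitor gilteritinib were compared in mice engrafted with MOLM14, an acute myeloid leukaemia cell line that carries an internal tandem duplication of FLT3 and a rearranged MLL gene. Gene counts were available for 8 libraries. Each combination of tissue label (bone marrow or liver), drug (gilteritinib or vehicle, 1 week) and diet (ketogenic or standard, 3 weeks) had 1 library, so no group had a replicate. The bone marrow libraries came from cells sorted for human CD45, and the other 4 were labelled as whole liver holding mouse and human cells. Library totals in bone marrow were 33611830 counts for vehicle with standard diet, 16290265 for vehicle with ketogenic diet, 15557885 for gilteritinib with standard diet and 20783534 for gilteritinib with ketogenic diet. In the libraries labelled liver the totals in the same order were 13605936, 16542212, 26499478 and 27657147, so depth there went with the drug. The tissue label coincided in all 8 libraries with a code in the library titles, which is read here as a batch. Tissue and batch therefore cannot be told apart.

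The libraries labelled liver held almost no hepatocyte transcripts among the counted human genes. Albumin (ALB) and transthyretin (TTR), abundant products of hepatocytes, had 0 counts in all 8 libraries, which for ALB allows at most 0.22 CPM in the shallowest library labelled liver. The summed hepatocyte identity genes reached 2.35 to 3.98 CPM in the libraries labelled liver and 2.71 to 5.34 CPM in bone marrow. Leukaemia cell markers summed to 15788 to 18282 CPM in the libraries labelled liver and to 16313 to 21463 CPM in sorted marrow. The text below refers to the libraries labelled liver throughout. No gene differed between the labels in an additive edgeR fit of all 8 libraries, where 2026 genes had an unadjusted p under 0.05, while 143 were called by DESeq2 and 3 by limma-voom. With separate drug and diet terms per label, edgeR called 518 genes between the labels, so the count of 0 depends on the model. Leaving out 1 library of the additive fit gave 38 calls without marrow vehicle with standard diet, 8 without marrow gilteritinib with ketogenic diet, 2 without either labelled-liver vehicle library and 10 without labelled-liver gilteritinib with standard diet.

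**Figure D1:**
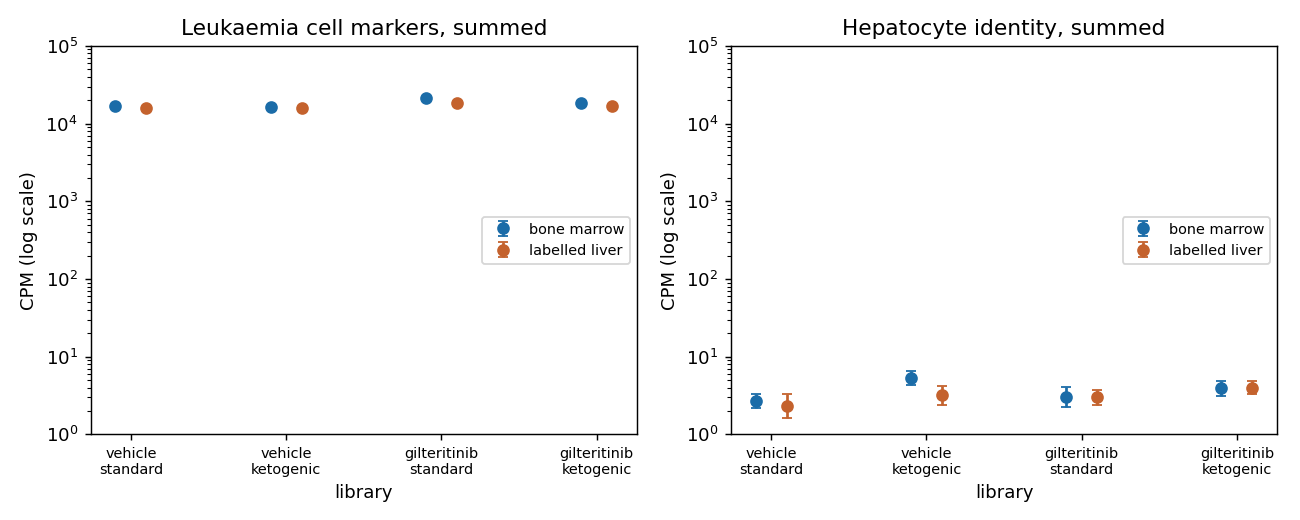
Summed CPM of leukaemia cell markers (left) and hepatocyte identity genes (right) in each of the 8 libraries, on a log axis, with points for bone marrow (blue) and the libraries labelled liver (orange) and bars for the exact Poisson 95% interval. Hepatocyte genes stayed between 2.35 and 5.34 CPM under both labels, against 15788 CPM or more for leukaemia markers.

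Markers of other cell types were also summed in the sorted marrow. The engrafted human cells were MOLM14, so cells carried over by the sort would be mouse. Sums over human genes therefore do not measure the purity of the sort. The libraries labelled liver held similar sums, at 90.0 to 108 CPM for lymphoid, 225 to 269 CPM for stromal and endothelial and 15.3 to 19.1 CPM for megakaryocyte markers. Erythroid markers had 5 counts in the library of vehicle with standard diet, or 0.149 CPM, and 0 counts in the other marrow libraries. Megakaryocyte markers summed to 16.8 to 23.5 CPM. Lymphoid markers summed to 85.7 to 133 CPM, and to 19.1 to 37.8 CPM without NKG7. Stromal and endothelial markers summed to 250 to 319 CPM, and to 12.9 to 19.4 CPM without PECAM1, which leukaemia cells can express. Neutrophil granule markers summed to 2889 to 4754 CPM, led by PRTN3, and MOLM14 can itself express granule genes. Lymphoid sums were higher in both gilteritinib libraries, with or without NKG7. Kupffer cell and macrophage marker sums were higher there too, at 81.9 and 92.3 CPM against 43.9 and 35.8 CPM. Without CSF1R they were 33.6 and 37.1 CPM against 15.1 and 15.5 CPM. Stromal sums were higher there with PECAM1 and lower without it, at 14.3 and 12.9 CPM against 19.4 and 17.7 CPM. Granule sums were highest with gilteritinib and ketogenic diet.

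The first comparison asked what gilteritinib changed in the sorted marrow cells. Cell cycle genes fell together: 33 of 34 proliferation genes fell, with a median log2 fold change of -1.02. Camera with an estimated correlation gave an adjusted p = 0.635, but on 1 residual degree of freedom it had little power to call any list. The topoisomerase TOP2A fell by 1.55 on the log2 scale (SE 0.11, edgeR adjusted p = 4.5e-15) and MKI67, a marker of cycling cells, fell by 1.01 (SE 0.12, edgeR adjusted p = 1.05e-08). Monocyte and macrophage genes moved the other way, and 16 of 22 myeloid differentiation genes rose, with a median of 0.81 and an adjusted p = 0.635 with an estimated correlation. The scavenger receptor CD163 (ENSG00000177575, chromosome 12, 7470813 to 7503893, GRCh38) rose by 2.53 (SE 0.22), from 3.17 to 15.8 CPM under the standard diet. Lysozyme (LYZ) rose by 1.40 (SE 0.12), the integrin ITGAM by 0.98 (SE 0.11) and the receptor CSF1R by 1.22 (SE 0.14).

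FCN1, a secreted lectin of monocytes, rose by 4.23 (SE 0.38) at a mean log2 CPM of 1.66. Among genes with a mean log2 CPM of at least 2, the largest rise was that of MMP9, a matrix metalloproteinase of neutrophils and macrophages, at 3.19 (SE 0.29), followed by CD163 and by the chemokine CCL23 at 1.86. The myeloid hexokinase HK3 rose by 1.61. HS3ST4, ADAMTS10, GNLY, CD48, H2BC12 and OLIG1 rose by 1.49 to 1.65. The immediate early transcription factor EGR1 fell by 2.46 on the log2 scale (SE 0.15, edgeR adjusted p = 7.31e-17), from 35.3 and 48.2 CPM to 6.07 and 9.10 CPM. AGT, the mitochondrial folate enzyme ALDH1L2 and the stearoyl-CoA desaturase SCD fell by 1.67 to 1.76. The mitotic genes CDCA2, CENPI, CKAP2L, KIF14 and MELK fell by 1.61 to 1.68.

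Of 55 cytosolic ribosomal protein genes 50 rose, with a median of 0.44, led by RPL26 (0.83), with an adjusted p = 0.635 with an estimated correlation. Of 23 integrated stress response genes 16 fell and 1 rose, among them the serine synthesis enzymes PHGDH (-1.39) and PSAT1 (-1.15), CHAC1 (-2.08) and the cystine transporter SLC7A11 (-2.33, at a mean log2 CPM of 0.93), and the list had an adjusted p = 0.635 with an estimated correlation. Of 24 cholesterol synthesis genes 13 fell, with SQLE at -0.84 and ACAT2 at -0.83, and an adjusted p = 0.635 with an estimated correlation. The STAT5 targets, downstream of FLT3 signalling, moved both ways: CISH (-0.54), CDC25A (-0.46), PIM1 (-0.43) and SOCS2 (-0.34) fell, MYC and CCND2 (0.34) rose, and 10 of 16 were not called, at a median of 0.037. Adjusted over the list alone, 3 rose and 4 fell, with an adjusted p = 0.909 with an estimated correlation. In the MAPK output list EGR1 and ETV4 fell, PHLDA1, CCND1, FOSL1 and ETV5 rose, and 12 of 18 were not called. Adjusted over the list alone, 5 rose and 3 fell, with an adjusted p = 0.885 with an estimated correlation. MYC rose by 0.39 (SE 0.11) and the ketone-using enzyme OXCT1 fell by 0.78 (SE 0.12). The receptor AXL fell by 0.46 (SE 0.14) and CD33 rose by 0.41 (SE 0.11). FLT3 itself was at 0.071 (SE 0.11), PTPRC at -0.19 (SE 0.11) and DUSP6 at 0.24 (SE 0.12), none of them past the threshold.

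In all, 2850 of 14029 tested genes were called in marrow (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1473 higher and 1377 lower with gilteritinib. Adjusted over the list alone, 34 proliferation genes fell, 16 myeloid genes rose, 53 ribosomal protein genes rose, 16 stress response genes fell and 17 cholesterol synthesis genes fell. By camera with a preset correlation, 13 of 30 lists were called. There the 5 lists just named had adjusted p-values from 3.1e-61 (proliferation) to 2.5e-07 (cholesterol synthesis). That test assumes a correlation of 0.01 between members. On 1 residual degree of freedom the correlation was estimated at -0.039, 0.0040 and -0.014 for the myeloid, stress response and cholesterol synthesis lists. For proliferation and ribosomal proteins it was estimated at 0.88 and 1. A correlation that high would make their preset p-values far too small. No list was called with an estimated correlation, where these 5 lists had an adjusted p = 0.635, but that test had little power. Fry called 3 lists: cholesterol synthesis (adjusted p = 0.038) and fatty acid synthesis (0.041) as lower, and NRF2 and glutathione (0.041) as higher. It did not call proliferation (adjusted p = 0.226), myeloid differentiation (0.084), ribosomal proteins (0.271) or the stress response (0.105). The gene test also rests on 1 residual degree of freedom. A fit of all 8 libraries with separate terms per label called 2459 genes, and leaving 1 library out of it, with no spread left within marrow, gave 1709 (vehicle with standard diet), 869 (vehicle with ketogenic diet), 1714 (gilteritinib with standard diet) or 853 (gilteritinib with ketogenic diet) called genes. DESeq2 called 1159 genes. With library totals as the scaling, 874 genes were higher and 2774 lower, since that scaling moved the median of all genes to -0.15.

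The second comparison asked what gilteritinib changed in the libraries labelled liver. LYZ rose by 1.77 (SE 0.14), from 1674 and 1959 CPM to 6349 and 6025 CPM, and FCN1 rose by 4.12 (SE 0.32), as it did in marrow. Of the 5 tested Kupffer cell and macrophage markers 3 rose, CD163 (1.14), ADGRE1 (0.70) and CSF1R (0.52), and the sorted marrow cells express the same genes. Immediate early genes rose, with JUN at 1.29 (SE 0.16), the phosphatase DUSP1 at 1.14 (SE 0.13) and FOSB at 1.11 (SE 0.13), and 9 of 20 members of the stress and dissociation list were called higher. The signalling regulators RGS1 and RGS2 rose by 2.73 and 2.16, the oxysterol receptor GPR183 by 1.84, the cytokine OSM by 1.64, FCER2 by 1.67 and FBP1 by 1.57. The immunoglobulin genes JCHAIN and IGLC2 rose by 3.03 and 2.12 from under 2.4 CPM, and IGLC2 shares sequence with other light chain genes.

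Fewer genes fell in these libraries. SCD fell by 1.00 (SE 0.15), the phosphatase PTP4A3 by 0.93 (SE 0.13) and PDGFRB by 1.06, and BMP8A, GJA3, KBTBD7, MDK, TRIM32 and NTSR1 fell by 0.88 to 1.38. Of 34 proliferation genes 2 fell, PLK1 (-0.46) and CCNB1 (-0.46), at a list median of -0.15. Of 30 interferon response genes 2 fell, IFIT5 (-1.05) and IRF7 (-0.62), at a list median of -0.27. ITGAM rose by 0.61, while MKI67 was at -0.20 (SE 0.13), PIM1 at -0.13 (SE 0.12) and MYC at -0.25 (SE 0.13).

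In the libraries labelled liver 318 of 14092 genes were called (edgeR), 199 higher and 119 lower. The drug ratios within each diet agreed less here than in marrow. Across genes with a mean log2 CPM of at least 2, their Pearson r was 0.29 here and 0.72 in marrow. At a mean log2 CPM of at least 4, 27 genes lay 2-fold or more apart under the standard diet and 12 under the ketogenic diet. In marrow these counts were 140 and 163. Adjusted over the list alone, 6 proliferation genes fell, 7 interferon genes fell and 1 rose, 10 stress and dissociation genes rose and 4 Kupffer cell and macrophage markers rose. By camera with a preset correlation 7 of 29 lists were called, and none with an estimated correlation (adjusted p = 0.821 for each). The fit of all 8 libraries with separate terms called 155, and leaving 1 library out of it, with no spread left within this label, gave 37 (vehicle with standard diet), 48 (vehicle with ketogenic diet), 40 (gilteritinib with standard diet) or 55 (gilteritinib with ketogenic diet) calls, and DESeq2 called 49.

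**Figure D2:**
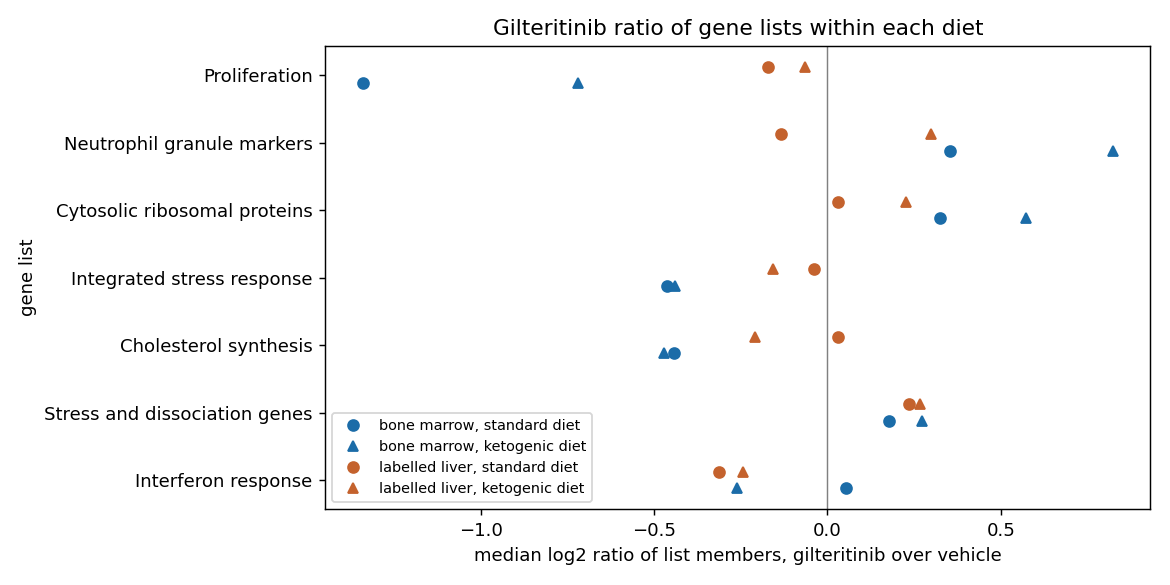
Median log2 ratio of gilteritinib over vehicle for the members of 7 gene lists, computed within the standard diet (circles) and within the ketogenic diet (triangles), for bone marrow (blue) and the libraries labelled liver (orange). Each point compares 1 library with 1 library. Proliferation lay at -1.34 and -0.72 in bone marrow and at -0.17 and -0.065 in the libraries labelled liver.

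The drug calls of the label sets, which share no libraries, overlapped. Of the genes tested under both labels, 118 were called higher in both, against 19.3 for independent lists, and 59 were called lower in both, against 11.7. Across 10076 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.42 and a Spearman rho of 0.37. A fit of all 8 libraries with 1 drug term, chosen after the data had been examined, called 725 of 14749 genes (edgeR), 442 higher and 283 lower, and 707 of them moved the same way in all 4 pairs of libraries. The fit made its calls from these same pairs, so their agreement is not a separate check. LYZ was 3.01-fold higher (log2 1.59, SE 0.10, adjusted p = 2.02e-06, 4 of 4 pairs), and HK3, FCER2, LGALS2, RNASE3 and PTAFR were higher and PTP4A3 lower in 4 of 4 pairs. In this fit 13 of 22 myeloid differentiation genes rose, or 15 adjusted over the list alone, and 6 of 34 proliferation genes fell, or 25 adjusted over the list alone. With an estimated correlation these lists had an adjusted p = 0.308 and an adjusted p = 0.448. Leaving out a marrow library gave 234 (vehicle with standard diet), 270 (vehicle with ketogenic diet), 265 (gilteritinib with standard diet) or 291 (gilteritinib with ketogenic diet) calls, and leaving out a labelled-liver vehicle library gave 2036 (standard diet) or 334 (ketogenic diet).

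The third comparison asked what the ketogenic diet changed in the sorted marrow cells. Of 24 fatty acid oxidation genes 4 rose and 20 were not called, or 5 rose adjusted over the list alone, with an adjusted p = 0.672 with an estimated correlation. Of 14 fatty acid synthesis genes 1 fell, and 1 adjusted over the list alone, with an adjusted p = 0.672 with an estimated correlation. CPT1A (ENSG00000110090, chromosome 11, 68754620 to 68844410, GRCh38), which attaches long-chain fatty acids to carnitine, rose by 1.22 (SE 0.13, edgeR adjusted p = 4.55e-09), from 25.4 to 69.0 CPM under vehicle and from 33.9 to 66.9 CPM under gilteritinib. The carnitine carrier SLC25A20 rose by 0.93 (SE 0.12) and the thiolase ACAA2 by 0.81 (SE 0.12), and ACADVL rose by 0.60 and ECH1 by 0.58. SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834, GRCh38) fell by 1.77 (SE 0.14, edgeR adjusted p = 5.74e-13), from 24.7 to 7.86 CPM under gilteritinib.

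Of 22 glycolysis genes 2 fell in marrow, HK2 by 0.71 (SE 0.13) and the glucose transporter SLC2A1 by 0.61 (SE 0.13), and 20 were not called. Adjusted over the list alone 3 fell, with an adjusted p = 0.672 with an estimated correlation. ARRDC4, which responds to glucose, fell by 0.72. Of 6 tested neutrophil granule markers 1 rose, MPO (0.78), and 5 were not called. Adjusted over the list alone 4 rose and 1 fell, with an adjusted p = 0.672 with an estimated correlation. MS4A3 rose by 0.80, MCEMP1 by 0.84 and IMPA2 by 0.89. LILRB3, SCARA5 and SMCO4 rose by 0.79 to 1.33, and PDE3A, TOX, BTG2, GPAT3, TGFBR1 and the ketone enzyme BDH1 fell by 0.55 to 0.75. MKI67 rose by 0.70 (SE 0.12), the only member of the proliferation list called over all genes, at a list median of 0.17. The class II gene HLA-DRA fell by 0.47. Of the 13 protein-coding mitochondrial DNA transcripts 2 rose, MT-ATP8 (0.57) and MT-ND4L (0.51), and all 13 when adjusted over the list alone, at a median of 0.41, with an adjusted p = 0.672 with an estimated correlation. The same list had a median of -0.059 in the libraries labelled liver. In marrow mitochondrial transcripts took 11.8% and 13.0% of counts with the ketogenic diet against 9.28% and 10.2% without. OXCT1 was at -0.30 (SE 0.12), FLT3 at -0.28 (SE 0.11) and MYC at 0.10 (SE 0.11).

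PDK4, the kinase that restrains pyruvate oxidation, was near the count floor. It had 36 and 23 reads in the ketogenic marrow libraries against 1 and 0 in the standard ones, a ratio of 78.2 (95% interval 13.5 to 3142), and 17 and 29 against 2 and 1 in the libraries labelled liver, a ratio of 13.9 (95% interval 4.47 to 69.9). These intervals cover counting error only.

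The diet test in marrow called 69 of 14029 genes (edgeR), 48 higher and 21 lower. By camera with a preset correlation 15 of 30 lists were called, and none with an estimated correlation. The count was unstable: 22 with DESeq2, 133 with upper-quartile factors and 1 without a low-count filter, and with relative log expression factors 35 of 42 calls were higher. Without the drug term 0 genes were called. The drug effect then stays in the residual spread, so this 0 says little about the diet. The fit of all 8 libraries with separate terms called 24 genes, and leaving 1 library out of it, with no spread left within marrow, gave 128 without either vehicle library and 14 without either gilteritinib library.

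The fourth comparison asked the same of the diet in the libraries labelled liver. Of 24 fatty acid oxidation genes 5 rose and 19 were not called, with an adjusted p = 0.67 with an estimated correlation. SLC25A20 rose by 0.86 (SE 0.15), ACAA2 by 0.80 (SE 0.13) and CPT1A by 0.54 (SE 0.14, edgeR adjusted p = 0.014), and SCD fell by 1.05 (SE 0.15). The granule proteases CTSG, ELANE and AZU1 rose by 0.62, 0.54 and 0.48. FBLN1, SELENOP, HUNK, GPC3, BEX1, FNDC10, CSRP3 and DERL3 rose by 0.82 to 1.12, and IGLC2 rose by 1.04. SLC2A1 fell by 0.74 (SE 0.15). The class II transactivator CIITA fell by 0.98, HLA-DPA1 by 0.89, IL7R by 1.17 and BLNK by 1.12. Of 6 tested lymphoid markers 1 rose, JCHAIN (0.91), and 0 fell, or 1 and 0 adjusted over the list alone, at a median of 0.14 and an adjusted p = 0.67 with an estimated correlation. JCHAIN turned to -0.18 without either gilteritinib library. H2AC6, JAML, PPP1R16B, KSR1 and GRAMD2B fell by 0.95 to 1.11, ITGAM fell by 0.71 and CSF1R by 0.60.

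In these libraries 143 of 14092 genes were called (edgeR), 51 higher and 92 lower. Of 24 fatty acid oxidation genes 5 rose, of 19 PPARA targets 5 rose, and of 6 tested neutrophil granule markers 4 rose, with 5, 5 and 5 adjusted over the list alone. By camera with a preset correlation 14 of 29 lists were called, and none with an estimated correlation (adjusted p = 0.67 for fatty acid oxidation). The fit of all 8 libraries with separate terms called 36, and leaving 1 library out of it, with no spread left within this label, gave 18 (vehicle with standard diet), 23 (vehicle with ketogenic diet) or 1 (either gilteritinib library) calls. DESeq2 called 11 genes, and no gene was called without a low-count filter. No gene was called without the drug term either, where the drug effect stays in the residual spread.

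**Figure D3:**
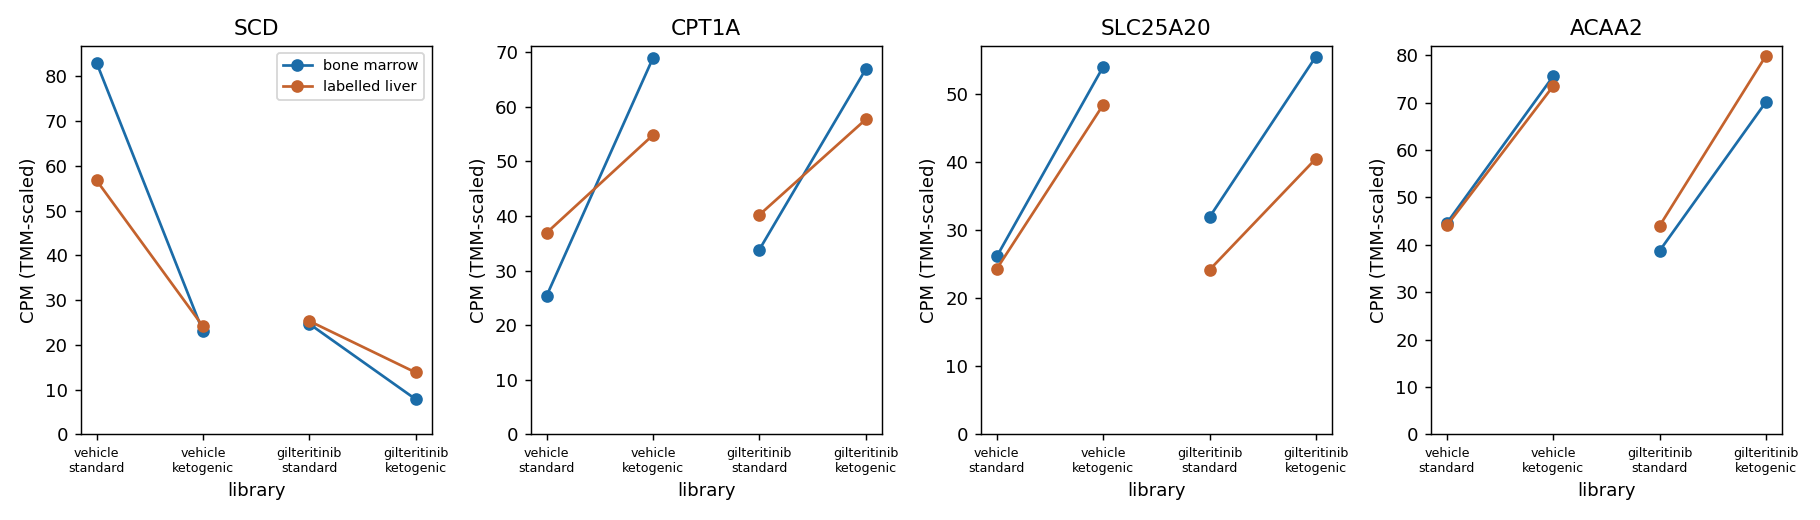
TMM-scaled CPM of SCD, CPT1A, SLC25A20 and ACAA2 in each of the 8 libraries, with lines joining the standard and ketogenic library of the same drug arm, for bone marrow (blue) and the libraries labelled liver (orange). SCD was lower and the other 3 genes were higher in the ketogenic library of each of the 4 pairs.

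Diet calls were shared between the label sets beyond independent lists, with 12 genes higher in both against 0.17 and 10 lower in both against 0.13. The shared genes included PDK4, CPT1A, SLC25A20, ACAA2, ACADVL, ECH1, IMPA2, FCGRT, MCEMP1, MS4A3, LRP5 and C1orf162, all higher, and SCD, SLC2A1, ARRDC4, PDE3A, GPR183, SORT1, HLA-DRA and SDC2, all lower. Across 10076 genes the log2 fold changes had a Pearson r of 0.36 and a Spearman rho of 0.32. The fit of all 8 libraries, chosen after the data had been examined, called 20 of 14749 genes for diet (edgeR), 12 higher and 8 lower, all 20 with the same direction in 4 of 4 pairs. Here too the calls came from these same pairs, so the agreement is not a separate check. SCD was at -1.39 (SE 0.18), CPT1A at 0.89 (SE 0.13), ACAA2 at 0.81 (SE 0.086) and the lipid droplet protein PLIN2 at 0.55 (SE 0.10). DESeq2 called 47 genes and edgeR without a low-count filter 33. In bone marrow, leaving out vehicle with standard diet gave 6 calls and gilteritinib with standard diet 7. Among the libraries labelled liver, leaving out vehicle with standard diet gave 115 calls, vehicle with ketogenic diet 4, gilteritinib with standard diet 9 and gilteritinib with ketogenic diet 6. As many genes or more were called in 4 of the 35 splits of the 8 libraries into 4 and 4. These include the drug split, which carries a drug effect, so the share cannot decide on a grouping by chance, which is not excluded.

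The last comparison set the combination against each single treatment, as ratios between single libraries with no replicate check. In marrow, gilteritinib with ketogenic diet against vehicle with standard diet put SCD at -3.39 (counting interval -3.65 to -3.17), EGR1 at -1.94, TOP2A at -1.70 and PTP4A3 at -1.89, and EPX at 1.93, FCER2 at 1.82, MPO at 1.70, LYZ at 1.64 and MS4A3 at 1.63. The same contrast in the libraries labelled liver put SCD at -2.03 (counting interval -2.22 to -1.86), PTP4A3 at -1.37, FCER2 at 1.95, LYZ at 1.85 and MS4A3 at 1.76. Among genes with a mean log2 CPM of 4 or more, 213 in marrow and 22 in the libraries labelled liver lay 2-fold or more apart in this contrast. Adding the diet to gilteritinib put 10 genes that far apart in marrow and 7 in the libraries labelled liver, and adding gilteritinib to the diet 163 and 12.

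The diet ratios within each drug arm compare 1 library with 1 library, and a difference between the arms was not tested for these lists. In marrow, neutrophil granule markers had a median log2 ratio of 0.15 for diet under vehicle and 0.88 under gilteritinib, with EPX at 1.62, PRTN3 at 1.18 and MS4A3 at 1.18 in the second. In the libraries labelled liver the same list stood at 0.19 and 0.74. Proliferation genes in marrow stood at 0.0028 for diet under vehicle and 0.34 under gilteritinib. The same list stood at 0.078 and 0.12 in the libraries labelled liver. Fatty acid synthesis genes in marrow lay at -0.20 and -0.39, and at -0.22 and -0.19 in the libraries labelled liver. Across genes, the diet ratios of both drug arms had a Pearson r of 0.24 in marrow and 0.21 in the libraries labelled liver, and they share no library.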

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

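The tests of the liver label, of 1 library left out, of tissue or batch, of heat shock genes and of the label splits were chosen after the result was seen. Those of depth and scaling, of the drug and diet splits and of the label swaps had their predictions written before. The thinning, the fit behind the splits and the tests between labels were themselves added after the data had been examined. Their predictions were therefore not fixed ahead of the data.

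The libraries labelled liver held almost no hepatocyte transcripts. Mouse liver reads counted on human genes would raise hepatocyte genes far above marrow, but their mean CPM was 0.836 times that of bone marrow. These sums also define the pattern, so the value restates it and is not a separate test. It shows only that no excess of reads was counted on these genes. Removal of mouse reads before counting may account for the pattern and stays open: leukaemia marker CPM stood at 0.915 times that of marrow, and no value of a table of human genes could exclude it. A wrong tissue label also stays open, because the 2026 genes with an unadjusted p under 0.05 between the labels would follow from batch or tissue as well. Explanations beyond these were not examined. The splits of the label test nothing, since a real count of 0 is reached by all 35 of the 35 splits, and the highest other, 345, is the drug split.

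Gilteritinib changed 367 genes differently under the labels (edgeR, unadjusted p under 0.05 for 2231), 128 with a higher effect in bone marrow and 239 with a lower one. EGR1 had the smallest p, with a log2 fold change of -2.46 in bone marrow and 0.045 in the libraries labelled liver. Only 8 swaps of the tissue label exist, too few for a share under 0.05. The real labels gave 367 and the highest other swap 424, and 2 of the 8 swaps, the real one included, reached 367 or more. The swap with 424 exchanged the labels of both vehicle groups. Its contrast is then the difference between the labels across both drugs, so it is not a grouping free of effects. For diet 0 genes differed (edgeR, unadjusted p under 0.05 for 712), and all 8 of the 8 swaps gave 0.

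Proliferation genes fell more with gilteritinib in bone marrow, by list medians that differed by -0.87. With all libraries thinned to the smallest total the difference was -0.85. Thinning keeps the expected share of each gene, and these genes are abundant, so the value could hardly move. It shows that the difference does not need the deeper counts. It cannot exclude differences between libraries that go with depth. Scaling is argued against, since the difference nearest 0 under other scalings was -0.85. A single marrow library is argued against, since the highest marrow median with 1 library left out was -0.72. Tissue and batch cannot be told apart, because the labels tie them together in every library, so a candidate explanation by tissue remains a hypothesis next to the -0.87.

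Immediate early genes rose with gilteritinib in the libraries labelled liver, 9 of 12 with a median of 0.65. Handling stress that induces heat shock genes is argued against: 0 of 8 heat shock members rose (edgeR) and their median was 0.038. A single library is argued against, since the lowest median with 1 library left out was 0.45. Handling without heat shock induction, batch and tissue were not separated and may each contribute to the 0.65 beside the 0.45. In bone marrow 6 of the same 12 genes rose and 1 fell.

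By camera with a preset correlation, 13 of 37 gene lists differed between the labels for drug and 9 for diet. None of the 37 lists was called with an estimated correlation (adjusted p = 0.508 or higher for drug and 0.749 or higher for diet). That test had little power with so few residual degrees of freedom. Fry also called 0 lists for drug and 0 for diet (adjusted p = 0.052 or higher for drug and 0.708 or higher for diet). The list differences below were therefore called with the preset correlation alone. For gilteritinib, the median member difference, bone marrow minus labelled liver, was -0.79 for proliferation, 0.31 for myeloid differentiation, 0.13 for nuclear oxidative phosphorylation, 0.27 for mitochondrial DNA transcripts, -0.39 for ketone body metabolism and -0.29 for cholesterol synthesis. It was -0.38 for the integrated stress response, 0.32 for ribosomal proteins, -0.34 for stress and dissociation genes, 0.44 for neutrophil granule markers, 0.23 for Kupffer cell and macrophage markers, 0.22 for leukaemia cell markers and 0.58 for liver fibrosis genes. For the diet it was -0.21 for MYC targets and ribosome biogenesis, 0.068 for proliferation, 0.38 for myeloid differentiation, 0.48 for mitochondrial DNA transcripts, -0.13 for cholesterol synthesis, 0.31 for MHC class II, -0.068 for ribosomal proteins, 0.10 for stress and dissociation genes and 0.58 for Kupffer cell and macrophage markers.

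The drug count of 725 over all 8 libraries was reached by 1 of the 35 splits, the real one, and the highest other called 3. These splits ignore the cells of label and diet, and the other splits had no drug term, so the drug effect stayed in their residual spread. Drug swaps within the cells number 8, too few for a share under 0.05, so whether chance is excluded stays open. The diet count of 20 was reached by 4 of the 35 splits, the highest other calling 1232. Some of these splits carry effects of the design. The drug split, tested as diet in a fit with 3 terms instead of 4, called 535. The split of marrow vehicle and labelled-liver gilteritinib against the rest called 133, and it follows the difference in drug effect between the labels. The share therefore cannot decide on chance, which is not excluded. The split with 1232 points to a structure of the libraries that was not tested.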

How the results depend on the processing

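Thinning, the fits of all 8 libraries with common terms and their alternatives, and the label tests were chosen after the data were seen. The cause was not tested for any change below. A fit without the drug term leaves the drug effect in the residual spread, so its diet count of 0 says little about the diet. Counts per label without 1 library come from the fit of all 8 libraries with separate terms and have no spread left within that label. The marrow drug count of 2850 became 1159 with DESeq2, 1221 without a low-count filter, 1671 without the diet term and 853 to 1714 without 1 library. The marrow diet count of 69 became 22 with DESeq2, 42 with relative log expression factors, 133 with upper-quartile factors, 1 without a filter, 113 with thinned counts, 0 without the drug term, 24 in the fit of all 8 libraries and 14 to 128 without 1 library. In the libraries labelled liver, the drug count of 318 became 49 with DESeq2, 35 without a filter, 29 without the diet term, 155 in the fit of all 8 libraries and 37 to 55 without 1 library. The diet count of 143 became 11 with DESeq2, 74 with upper-quartile factors, 0 without a filter, 95 with thinned counts, 0 without the drug term, 36 in the fit of all 8 libraries and 1 to 23 without 1 library. With common terms, the drug count of 725 became 234 to 2036 without 1 library, and the diet count of 20 became 47 with DESeq2, 33 without a filter and 4 to 115 without 1 library. The label count of 0 became 143 with DESeq2, 3 with limma-voom, 10 without a filter, 518 with separate terms and 0 to 38 without 1 library.

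With an estimated correlation 0 lists were called in each of the 4 comparisons, and by fry 3 for drug and 2 for diet in bone marrow and 0 and 0 in the libraries labelled liver. The test with an estimated correlation had little power on 1 residual degree of freedom. In the libraries labelled liver, ATF3 with gilteritinib ranged from -0.062 to 1.67 without 1 library and reversed without vehicle (-0.061) or gilteritinib (-0.062) of the standard diet. JCHAIN with diet there ranged from -0.18 to 1.15 and reversed without either gilteritinib library. In these libraries the log2 ratio of leukaemia markers, gilteritinib over vehicle, was 0.15 per library total and -0.17 per hepatocyte count. The second value divides by hepatocyte sums of 32 to 110 counts, which were no higher in CPM than in sorted marrow. It therefore does not measure leukaemia cells per liver cell, and its sign carries no meaning. Among the 105 genes followed for drug and the 28 for diet in bone marrow 0 values reversed over the alternatives run. Each value is 1 gene in 1 setting, and those without an adjusted p were left out. For drug 323 values were no longer past the threshold and 1343 stayed past it, and for diet 167 and 274. The alternatives on genes 8 times higher in liver, and on leukaemia markers 8 times higher in marrow, were not run, as 0 such genes existed.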

Other observations

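The comparisons of gene lists below were among those planned, and the genes named were chosen after their values were seen. In bone marrow, 4 of 13 NF-kB genes were called higher with gilteritinib (edgeR; adjusted p = 0.635 with an estimated correlation), among them NFKBIA (0.82) and RELB (0.87), or 5 higher and 2 lower adjusted over the list alone, at a list median of 0.14. In the libraries labelled liver 1 of 13 was called higher, CCL3 (1.34), and 2 lower, TNF (-0.85) and TNFAIP3 (-0.60), or 4 higher and 2 lower adjusted over the list alone, at a median of 0.15 (adjusted p = 0.821 with an estimated correlation). The cholesterol efflux gene ABCA1 rose by 1.39 in bone marrow and stood at 0.76, not past the threshold, in the libraries labelled liver. The HOXA and MEIS1 programme, typical of MLL-rearranged leukaemia, had 1 member higher and 3 lower of 18 in bone marrow with gilteritinib (adjusted p = 0.828 with an estimated correlation). HLA-DMA (0.74) and HLA-DQB1 (0.58) rose with gilteritinib in bone marrow, where 5 of 11 MHC class II genes rose (adjusted p = 0.635 with an estimated correlation).

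The summed CPM of proliferation genes under vehicle was 4740 and 4669 in bone marrow and 4335 and 4646 in the libraries labelled liver, and under gilteritinib it was 2093 and 2477 against 4085 and 4148, each with standard and ketogenic diet in this order. Interferon response genes in bone marrow had a median log2 ratio for diet of 0.059 under vehicle and -0.38 under gilteritinib. The difference ran the other way in the libraries labelled liver, with -0.10 and 0.075. Each ratio is between single libraries.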
